A study of Mus musculus with 6 samples.

How the data were processed

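RNA was sequenced from 6 samples of sorted mouse cells, 4 controls and 2 heterozygous for a floxed Magoh allele. Per the labels' protocols, tdTomato-positive cells of the embryonic day 11.5 telencephalon were sorted by flow cytometry into lysis buffer and frozen. RNA was purified on columns, and libraries were made with a NuGEN mRNA kit whose globin depletion step was left out. Per the submitters' processing notes, Trim Galore, STAR, HTSeq and the mouse build mm10 were used, and the notes name no versions. The gene annotation used by the authors, the strandedness of the libraries and the counting settings are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies such as histone and protocadherin genes, cannot be assigned to a single gene with certainty.

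The authors deposited 2 tables. The first holds raw read counts for 38561 Ensembl genes, with 0 rows that name no gene. The second holds normalized values (a signal, in counts divided by a size factor) for 18065 genes, and the deposited values were checked to be the raw counts divided by a single factor per library. Those factors differed by at most 0.095% from median-of-ratios size factors computed from the counts. Each gene of the second table had at least 10 reads in a library, and 0 other genes did. Columns were matched to samples by the number and letter of the sample code, and 0 columns belonged to no sample.

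The raw counts were the basis of the comparison. Total counts were 37.9, 37.4, 44.2 and 43.8 M (in units of 1e+06) for controls 1 to 4 and 42.0 and 49.2 M for heterozygous libraries 1 and 2. A count of 0 in a library allows up to 3 counts, or 0.061 to 0.0802 CPM, and this floor covers counting error only, since the libraries carry no molecular identifiers. Of the file's gene IDs, 36639 matched GENCODE release M21 (GRCm38, the assembly behind mm10), which gave coordinates, current symbols, exon length and GC content.

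Genes were kept by edgeR's filterByExpr, which left 16495, and CPM were scaled by TMM factors. The main test was edgeR 4.0.16 (glmQLFit with robust fitting and glmQLFTest, two-sided, R 4.3.3), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. Whether the 6 samples came from separate embryos is not stated in the labels, so p-values measure only the spread between these samples. With 4 against 2 samples an exact permutation test of a single value cannot give a p below 0.0667 (two-sided).

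Gene lists were fixed before the data were examined: 36 by gene names and 8 by name patterns, of which 41 had at least 5 tested members. They cover medial ganglionic eminence (MGE) and interneuron genes, neighbouring brain regions, other cell types that the gate could hold, the cell cycle, p53 targets, RNA decay, stress and metabolism. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 41 lists, and camera with an estimated correlation and fry were run beside it. A list score is the mean log2 CPM of the members in a library minus the mean of that score over the controls.

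The rule for naming genes was also fixed beforehand. It takes Magoh, Magohb, Nkx2-1, Lhx6, Dlx2, Pafah1b1, Trp53, Cdkn1a, Mdm2, Ccng1, Xist and 4 Y-linked genes always. It adds passing genes with a mean of at least 1 CPM whose heterozygous libraries lie outside the control range. Since fewer than 10 passed, it took the 10 higher and 10 lower such genes with the smallest p, given as values and not as changed. From each described list it adds up to 4 members by smallest p. Genes with clone names are left out of the ranked genes, and some genes that the rule or an alternative names are not reported here.

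Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom with and without quality weights, limma-trend on log2 of the authors' normalized values plus 1, median-of-ratios (RLE) and upper-quartile scaling, no count filter or a mean of 1 CPM, edgeR without robust fitting, the number in the sample code as a block, Y-linked expression as a covariate, leaving out sex-linked and mitochondrial genes, other thresholds, and leaving out each library in turn. Alternatives chosen after seeing the data were the removal of each library's trend on exon length and GC content (loess, span 0.5), the share of rRNA-like reads as a covariate, and leaving out the 2 libraries without Y-linked reads together. Length and GC were known for 98.6% of tested genes.

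The scripts were tested on simulated counts drawn from the real means and dispersions for 4 against 2 libraries and 15904 genes. There edgeR recovered 22% of 100 genes changed by 2-fold and 78% of 100 changed by 4-fold, with 3 false calls. DESeq2 recovered 48% and 87% with 30 false calls, and limma-voom 22% and 77% with 2 false calls. The changed genes had a mean of at least 1 CPM, and no structure shared between libraries was simulated. Recovered shares and false calls may therefore differ in the data. In a simulated set of lists, with each gene drawn independently, the raised list was called and 0 of 40 unchanged lists were. In the data the estimated correlation of the called lists ran from 0.071 (S phase genes) to 0.634 (proteasome subunits). The simulation therefore does not show how often lists of correlated genes are called falsely.

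The explanations weighed in the closing section were written with their expected outcomes before or after the results they test, as stated there, and their grouping into patterns was set after the results were seen.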

Results

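Transcriptomes were measured in cells of the medial ganglionic eminence (MGE), the ventral forebrain region that gives rise to many cortical interneurons, to ask how the loss of a Magoh allele changes them. Magoh is a core protein of the exon junction complex, which marks spliced mRNAs. Cells were sorted at E11.5 (mid-gestation) by a tdTomato reporter that is switched on by Cre recombinase under Nkx2-1 control. There were 4 control libraries, with the Cre and reporter, and 2 heterozygous libraries, which also carried a floxed Magoh allele. Total counts ran from 37.4 to 49.2 M per library (M, counts in units of 1e+06), and 17078 to 19071 genes had at least 1 read.

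The libraries differed in ways that the genotype does not name. Control 2 and heterozygous library 1 had 0 reads from 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty), and Xist stood at 94.2 and 111 CPM. The other 4 libraries had 3453 to 4291 Y-linked reads and at most 0.549 CPM of Xist. By these sex-linked genes control 2 and heterozygous library 1 read as female, and the other 4 as holding male cells. The labels give no sex. In the same 2 libraries without Y-linked reads, long transcripts were lower relative to short ones. Sex and this length difference therefore cannot be told apart between the libraries. The median deviation of transcripts of 8000 nt or more, minus that of transcripts under 1000 nt, was -0.81 log2 units in control 2 and -0.34 in heterozygous library 1, against 0.15 to 0.48 in the others. Values are therefore also given within these 2 libraries (heterozygous 1 against control 2). They are given among the remaining 4 as well (heterozygous 2 against controls 1, 3 and 4). Neither contrast has replicates in both groups. The first is also not matched in the length difference, which was larger in control 2 than in heterozygous library 1.

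Magoh (ENSMUSG00000028609; chromosome 4, 107879755 to 107887424, plus strand, GRCm38) was lower in both heterozygous libraries than in every control, without passing the test. Its level was 81.0 ± 25.01 CPM in controls (SD, n = 4) and 52.8 ± 6.05 CPM in heterozygous cells (SD, n = 2), from 68.1, 118, 63.7 and 74.3 CPM in controls 1 to 4 and 57.1 and 48.6 CPM in the heterozygous libraries. The log2 fold change was -0.62 with a standard error of 0.28 (edgeR, adjusted p = 0.85). Within the 2 libraries without Y-linked reads the difference was -1.04 log2 units, which rests on control 2, the highest control. Among the other 4 it was -0.50. After removal of length and GC trends, chosen after seeing the data, the log2 fold change was -0.62 with a standard error of 0.13 (edgeR, adjusted p = 0.549). Leaving out control 2 reduced the log2 fold change to -0.37. Which exons the floxed allele loses is not given in the sources used here, so reads outside them may remain. The paralog Magohb stood at 9.95 ± 3.51 CPM in controls (SD, n = 4) and 10.3 ± 2.38 CPM in heterozygous cells (SD, n = 2), a log2 fold change of 0.05 with a standard error of 0.34 whose sign changed in 5 of 21 alternatives.

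No single gene passed the test between genotypes. With edgeR, 0 of 16495 genes passed (smallest adjusted p = 0.793), and 944 had an unadjusted p under 0.05, of which 288 were higher and 656 lower, against 825 expected by chance. DESeq2 called 75 genes, 7 higher and 68 lower, and limma-voom called 0. Of the 68 lower DESeq2 calls, 31 had 0 reads in both heterozygous libraries, and their control means were at most 1.08 CPM. The heterozygous libraries also had more genes without a read. Among genes that averaged 20 to 40 reads in the other libraries, 11.1% and 10.6% had 0 reads in them (exact 95% intervals 9.38 to 13.1% and 8.85 to 12.5%), against 0.43 to 3.93% in controls. Both heterozygous libraries lay outside the range of the 4 controls for 14.3% of genes, where chance gives 13.3%.

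Genes were ranked among those without clone names, with a mean of at least 1 CPM and with heterozygous libraries outside the control range. There the 10 higher genes with the smallest p included 3 targets of the tumour suppressor p53, described further on, and the transcription factors Sim1, Nkx2-2 and Prdm13. Sim1, a transcription factor of hypothalamic neurons, stood at 20.5 ± 4.05 CPM in controls (SD, n = 4) and 39.2 ± 6.59 CPM in heterozygous cells (SD, n = 2). Nkx2-2, a homeobox factor of the ventral neural tube, stood at 15.7 ± 2.003 and 27.4 ± 5.52 CPM, and Prdm13 at 7.64 ± 1.495 and 15.5 ± 1.53 CPM. Fam212b (now Inka2) had a log2 fold change of 1.65 ± 0.33 (SE), B4galnt1, a ganglioside synthase, 0.76 ± 0.19, and Crb1, an apical polarity protein, 0.73 ± 0.18. Each had an edgeR adjusted p of 0.793, and DESeq2 called Fam212b, Prdm13 and Sim1 but not Nkx2-2, B4galnt1 or Crb1. Over 21 alternatives the log2 fold change ran from 0.38 to 1.09 for Sim1 and from 0.50 to 0.99 for Nkx2-2.

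Among the 10 lower genes was Fgf8 (ENSMUSG00000025219; chromosome 19, 45736798 to 45742915), a secreted signal that patterns the forebrain. It stood at 9.91 ± 4.55 CPM in controls (SD, n = 4) and 1.38 ± 0.189 CPM in heterozygous cells (SD, n = 2), a log2 fold change of -2.85 ± 0.46 (SE). Frzb, a secreted Wnt antagonist, stood at 23.8 ± 2.49 and 10.1 ± 0.649 CPM, and Sepp1 (now Selenop), the plasma selenium carrier, at 58.4 ± 20.6 and 15.2 ± 2.32 CPM. Bcam, a laminin receptor, had a log2 fold change of -1.31 ± 0.27 (SE), Kcnn3, a calcium-activated potassium channel, -2.42 ± 0.52, and Aass, an enzyme of lysine breakdown, -1.63 ± 0.36. Mamdc2 (-2.27 ± 0.42), Syne4 (-2.23 ± 0.42), Nebl (-1.04 ± 0.22) and Wdr90 (-0.83 ± 0.16) completed the group. Each had an edgeR adjusted p of 0.793, and DESeq2 called all 10 lower. Over 21 alternatives the log2 fold change ran from -2.11 to -1.17 for Sepp1 and from -1.24 to -0.62 for Nebl.

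**Figure D1:**
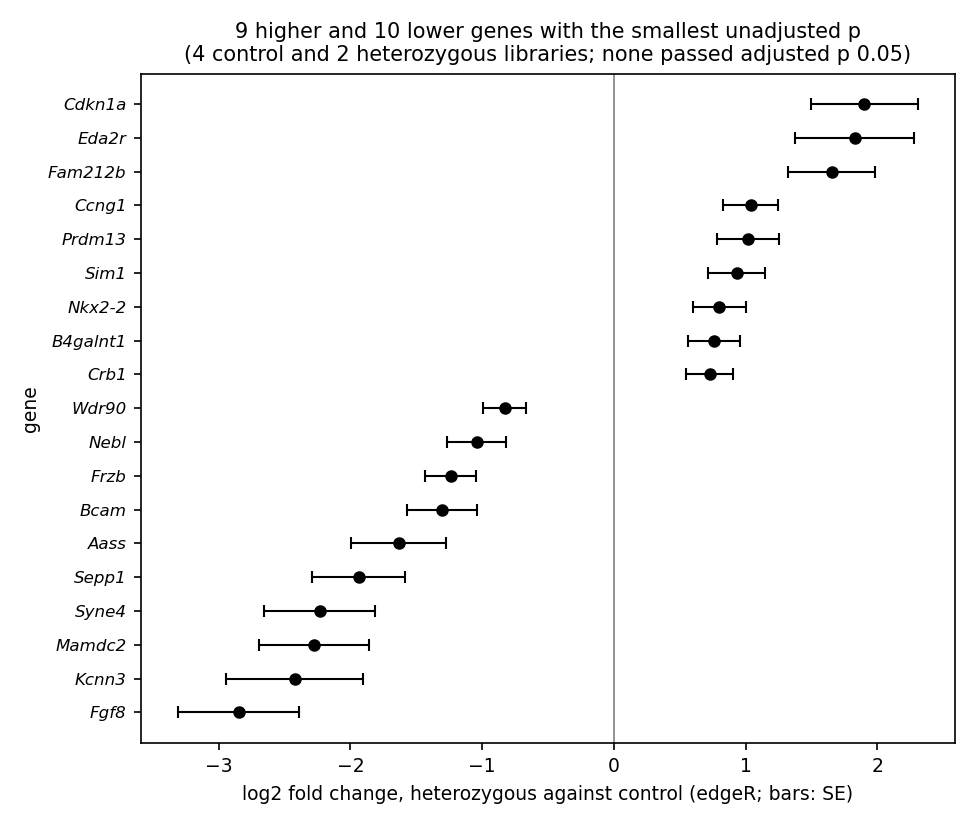
Log2 fold change (x axis, heterozygous against control, edgeR) of 9 higher and 10 lower genes (y axis) from 4 control and 2 heterozygous libraries, with bars for the standard error. They had the smallest p among genes without clone names, with a mean of at least 1 CPM and with heterozygous libraries outside the control range. Values ran from -2.85 for Fgf8 to 1.90 for Cdkn1a, and each gene had an adjusted p of 0.793.

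Target genes of p53 were higher as a group in heterozygous cells. Of 33 tested members, 27 had a log2 fold change above 0, with a median of 0.24 (camera, adjusted p = 2.52e-05). With an estimated correlation the list was not called (adjusted p = 0.745). Ccng1 (cyclin G1; ENSMUSG00000020326; chromosome 11, 40748552 to 40755311) stood at 42.7 ± 8.20 CPM in controls (SD, n = 4) and 87.6 ± 11.7 CPM in heterozygous cells (SD, n = 2). Cdkn1a (ENSMUSG00000023067; chromosome 17, 29090976 to 29100727), which encodes the cell cycle inhibitor p21, stood at 6.05 ± 3.07 and 22.6 ± 8.06 CPM. Eda2r, a receptor of the tumour necrosis factor family (ENSMUSG00000034457; chromosome X, 97333840 to 97377216), stood at 2.88 ± 1.46 and 10.2 ± 0.496 CPM.

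Over all genes, 0 members of the p53 list passed edgeR, and 3 passed when adjusted over the list alone: Ccng1 and Cdkn1a (adjusted p = 0.0278 each) and Eda2r (adjusted p = 0.041). DESeq2 called the same 3 over all genes. Mdm2, the ubiquitin ligase of p53, stood at 66.7 ± 5.67 CPM in controls (SD, n = 4) and 87.4 ± 0.0886 CPM in heterozygous cells (SD, n = 2), and Phlda3 at 9.44 ± 0.917 and 15.8 ± 7.05 CPM, without passing. Trp53 itself stood at 88.2 and 182 CPM in the 2 heterozygous libraries, on either side of the controls at 151 to 169 CPM. The list score was 0.29 and 0.49 in the heterozygous libraries and -0.12 to 0.16 in the controls. It was 0.23 higher in heterozygous library 1 than in control 2, and 0.51 higher in heterozygous library 2 than in controls 1, 3 and 4. Without heterozygous library 2 the median was 0.19 and the call was lost (adjusted p = 0.0601), and without heterozygous library 1 the median was 0.44. Over 21 alternatives the adjusted p ran from 7.73e-07 to 0.745.

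**Figure D2:**
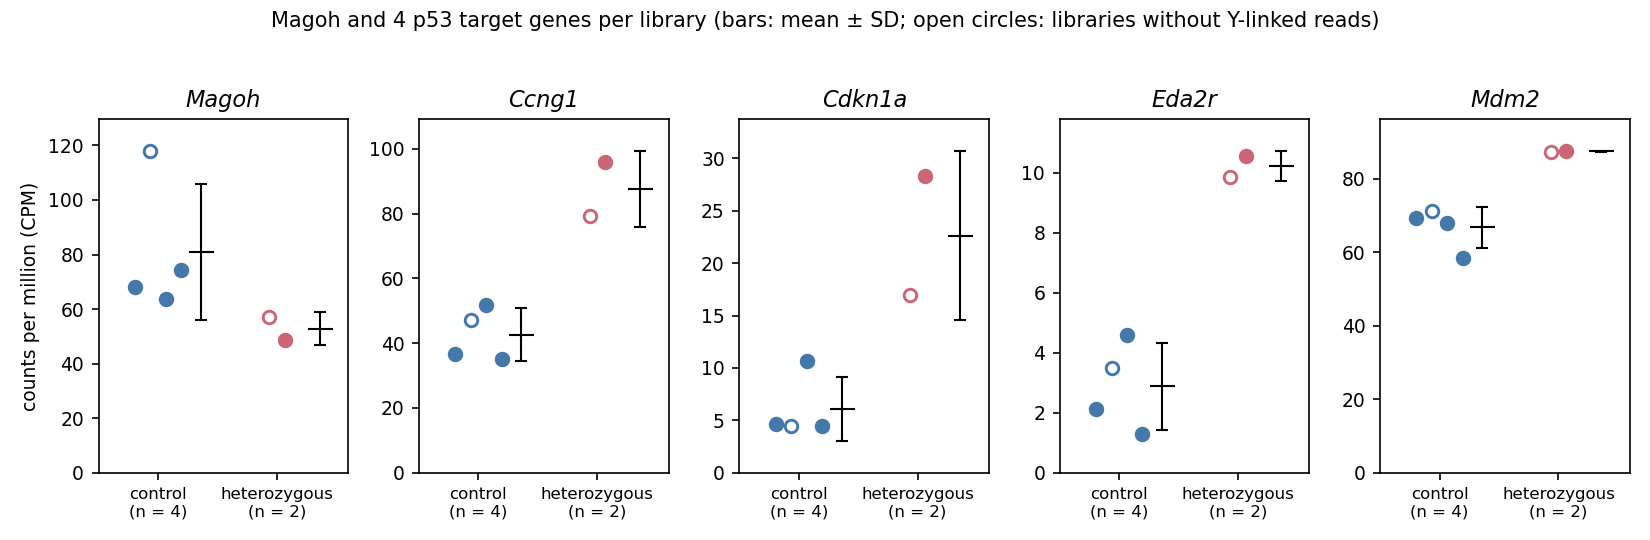
CPM (y axis, from 0) of Magoh and 4 p53 target genes in 4 control and 2 heterozygous libraries, 1 point per library, with the mean and SD of each group as a bar and open circles for the 2 libraries without Y-linked reads. Both heterozygous libraries lie below all controls for Magoh (57.1 and 48.6 CPM) and above all controls for Ccng1 (79.4 and 95.8 CPM), Cdkn1a, Eda2r and Mdm2.

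Pan-neuronal genes were also higher as a group. Of 31 members 28 had a log2 fold change above 0, with a median of 0.51 (camera, adjusted p = 3.4e-09), and the call was lost with an estimated correlation (adjusted p = 0.745). Among them, Elavl4, an RNA-binding protein of neurons, stood at 120 ± 22.8 CPM in controls (SD, n = 4) and 193 ± 10.9 CPM in heterozygous cells (SD, n = 2), and the transcription factor Nhlh1 at 32.0 ± 6.80 and 56.7 ± 0.339 CPM. Rbfox1 stood at 1.58 ± 0.517 and 4.02 ± 0.956 CPM, and Nhlh2 at 59.6 ± 13.02 and 101 ± 3.48 CPM. No member passed over all genes, and 0 passed when adjusted over the list alone (smallest adjusted p = 0.0711, edgeR), with 10 at an unadjusted p under 0.05 and 0 called by DESeq2. The score difference was 0.55 within the 2 libraries without Y-linked reads and 0.59 among the other 4. Control 1, at 0.43, lay above heterozygous library 1, at 0.29. Leaving out heterozygous library 2 lowered the median to 0.22 and kept the call (adjusted p = 0.0106, within a range of 8.48e-14 to 0.745 over 21 alternatives).

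Genes of postmitotic and migrating interneurons were called higher too, with 22 of 28 members above 0 and a median of 0.50 (camera, adjusted p = 0.000459, and adjusted p = 0.745 with an estimated correlation). This came from heterozygous library 2. Its list score was 0.83, while heterozygous library 1 stood at -0.01, among the controls at -0.18 to 0.25, and the median was -0.01 without library 2 and 0.91 without library 1. The adjusted p was 0.813 without library 2, the highest of 21 alternatives, of which the lowest was 1.63e-07. Lhx6, the transcription factor that specifies MGE interneurons, stood at 70.8 CPM in heterozygous library 1 and 243 CPM in library 2, against 82.8 ± 27.1 CPM in controls (SD, n = 4). Dlx2 stood at 346 and 657 CPM in the heterozygous libraries and 296 ± 92.4 CPM in controls (SD, n = 4). Within the list, Sst stood at 2.58 ± 1.15 CPM in controls (SD, n = 4) and 8.64 ± 4.78 CPM in heterozygous cells (SD, n = 2), and Calb1 at 29.3 ± 9.92 and 58.5 ± 18.5 CPM. Maf, which marks migrating interneurons, went the other way, at 31.2 ± 15.8 and 7.98 ± 6.52 CPM. Over all genes or adjusted over the list alone, 0 members passed. Nkx2-1, which controls the Cre that switches on the reporter, stood at 433 ± 98.5 and 407 ± 82.8 CPM.

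Cell cycle lists were lower. Of 53 genes of G2 and M phase, 48 had a log2 fold change below 0, with a median of -0.25 (camera, adjusted p = 0.000359), and 41 of 44 S phase genes were below 0, with a median of -0.16 (adjusted p = 0.0115). Neither call held with an estimated correlation (adjusted p = 0.745 for each). Ttk, a spindle checkpoint kinase, stood at 37.0 ± 6.67 CPM in controls (SD, n = 4) and 22.7 ± 1.86 CPM in heterozygous cells (SD, n = 2), Anln at 57.2 ± 14.5 and 35.6 ± 0.488 CPM, and Mcm6, a subunit of the replicative helicase, at 356 ± 19.5 and 280 ± 7.17 CPM. Ttk and Anln are among 11 of the 53 G2 and M phase genes for which both heterozygous libraries lay below all controls. Most of the list did not separate in this way. Over all genes it held for 1343 of 16495, where chance gives 6.67% on each side. The 62 replication-dependent histone genes had a median of -0.43 (adjusted p = 4.08e-05, and 0.86 with an estimated correlation). DNA repair and damage response genes had a median of -0.34 (27 members, adjusted p = 0.00172, and 0.745 with an estimated correlation), and mitotic spindle and microcephaly genes one of -0.53 (21 members, adjusted p = 0.0216, and 0.86 with an estimated correlation). In each of these 5 lists 0 members passed over all genes or adjusted over the list alone.

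Part of these differences was not seen within the 2 libraries without Y-linked reads. That contrast sets heterozygous library 1 against control 2, which are unequal in the length difference (-0.34 and -0.81). It therefore cannot exclude a genotype difference. There the G2 and M phase score differed by 0.02, DNA repair by -0.01, and the spindle list by 0.15, whereas among the other 4 libraries heterozygous library 2 was lower by 0.43, 0.37 and 0.46. The S phase score was lower in both contrasts (-0.10 and -0.27), as was that of the histones (-0.48 and -0.61). Heterozygous library 2 decided the S phase call (median -0.10 and adjusted p = 0.332 without it) and, with control 2, the histone call (medians of -0.15 and -0.24, adjusted p = 0.639 and 0.063), while without heterozygous library 1 the histone median was -0.75. The DNA repair call ended without heterozygous library 1 (median -0.31, adjusted p = 0.19). For the spindle list the call ended without control 1, control 3 or heterozygous library 1 (medians of -0.41, -0.30 and -0.23, adjusted p = 0.0922, 0.13 and 0.619). With Y-linked expression as a covariate the spindle list was not called (median -0.16, adjusted p = 0.117). The labels do not say what the number in the sample codes marks, and with it as a block the genotype difference rests on control 1 and heterozygous library 2, which share a number. With that block the calls of S phase (median -0.14, adjusted p = 0.465), DNA repair (median -0.25, adjusted p = 0.293) and the spindle list (median -0.45, adjusted p = 0.237) ended. Over 21 alternatives the adjusted p ran from 0.000339 to 0.745 for S phase, 5.86e-11 to 0.86 for histones, 4.21e-07 to 0.745 for DNA repair and 7.04e-07 to 0.86 for the spindle list.

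**Figure D3:**
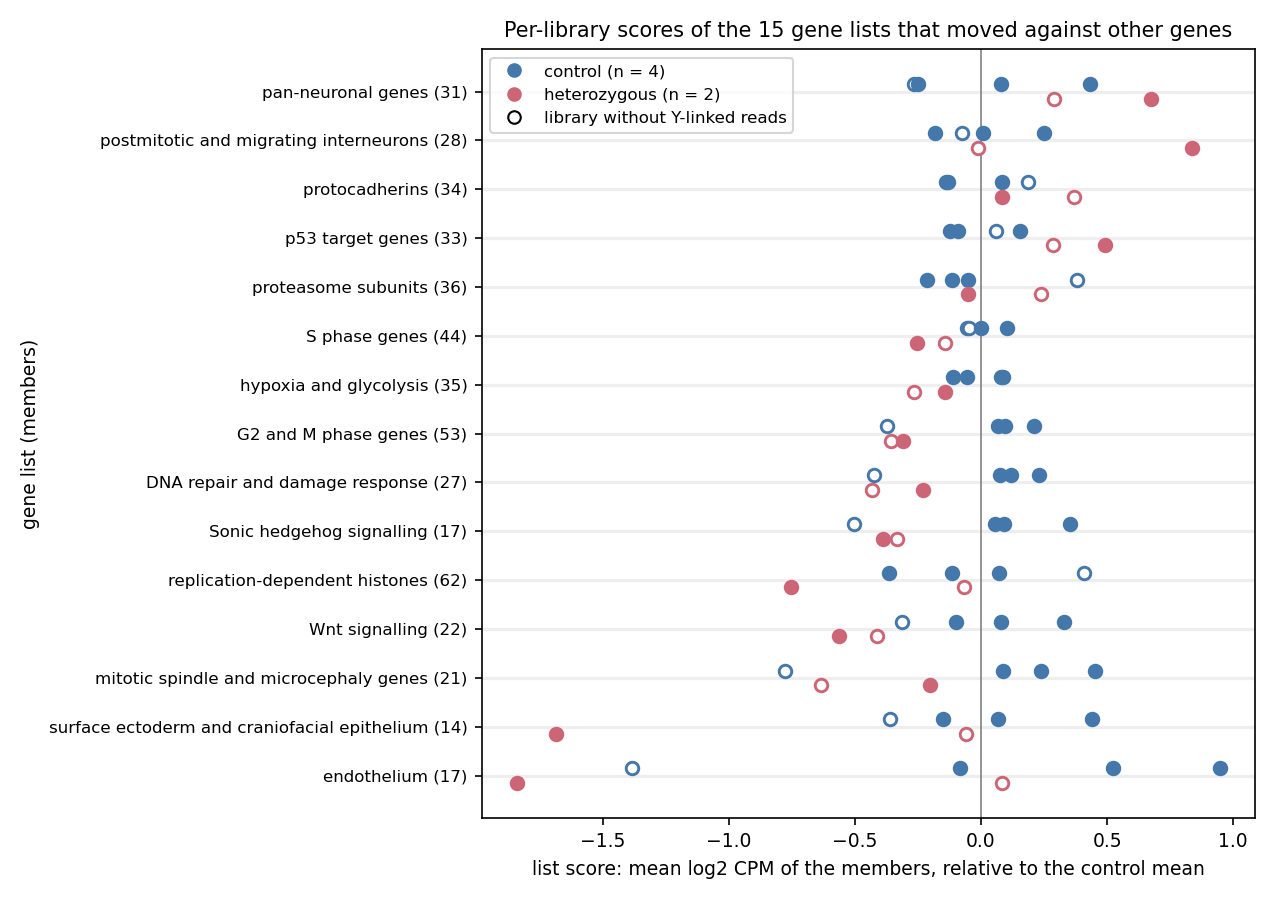
List score (x axis, mean log2 CPM of the members relative to the control mean) of the 15 gene lists called by camera (y axis, with the number of tested members), 1 point per library, with open circles for the 2 libraries without Y-linked reads. For p53 targets both heterozygous libraries (0.29 and 0.49) lie above all 4 controls, while for G2 and M phase genes control 2 (-0.37) lies with the heterozygous libraries (-0.36 and -0.31).

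Genes of 2 patterning pathways were lower. Of 22 Wnt signalling genes, 19 had a log2 fold change below 0, with a median of -0.46 (camera, adjusted p = 0.000497, and 0.745 with an estimated correlation). The transcription factor Tcf7 stood at 8.54 ± 4.31 CPM in controls (SD, n = 4) and 2.19 ± 0.761 CPM in heterozygous cells (SD, n = 2), the receptor Fzd5 at 130 ± 22.8 and 73.7 ± 20.5 CPM, and the inhibitor Dkk1 at 6.97 ± 3.96 and 1.94 ± 0.851 CPM. Of these DESeq2 called Tcf7. Of 17 Sonic hedgehog signalling genes, 16 were below 0, with a median of -0.34 (adjusted p = 0.02, and 0.86 with an estimated correlation), Hhip at 10.9 ± 3.78 and 5.91 ± 0.590 CPM and Gli1 at 13.3 ± 3.18 and 8.34 ± 2.07 CPM among them. In both lists 0 members passed edgeR over all genes or adjusted over the list alone. Within the 2 libraries without Y-linked reads the Wnt score differed by -0.10 and the hedgehog score by 0.17. Among the other 4 they differed by -0.67 and -0.56. Without heterozygous library 2 the Wnt call was lost (median -0.30, adjusted p = 0.0856), and the hedgehog call was lost without control 4, heterozygous library 1 or heterozygous library 2 (medians of -0.28, -0.43 and -0.47, adjusted p = 0.0834, 0.167 and 0.137). The hedgehog call was also lost with Y-linked expression as a covariate (median -0.28, adjusted p = 0.0875) and with the sample code number as a block (median -0.49, adjusted p = 0.137). The Wnt median was -0.20 without control 4. Over 21 alternatives the adjusted p ran from 1.8e-05 to 0.745 for Wnt and 0.000246 to 0.86 for hedgehog genes.

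Markers of cells outside the MGE lineage varied from library to library. Surface ectoderm and craniofacial epithelium genes were called lower (14 members, median -0.55, camera, adjusted p = 0.011, and 0.745 with an estimated correlation), with list scores of -0.06 and -1.68 in the heterozygous libraries. Cdh1 (E-cadherin) passed when adjusted over the list alone (adjusted p = 0.0429, edgeR), at 6.36 ± 1.254 CPM in controls (SD, n = 4) and 3.08 ± 0.0507 CPM in heterozygous cells (SD, n = 2). Grhl2 also passed over the list alone (adjusted p = 0.0429), with 0.334 CPM in controls and 0 reads in both heterozygous libraries, at least 10.1-fold lower by counting error alone (a floor of 3 counts over the group). With 6 to 17 reads per control, Grhl2 lies where these 2 libraries also had more genes at 0, so the bound does not cover a loss of molecules in library preparation. Endothelial genes were called lower (17 members, median -0.71, adjusted p = 0.0301, and 0.86 with an estimated correlation), with scores of 0.08 and -1.84 in the heterozygous libraries and -1.38 to 0.95 in controls. Without heterozygous library 2 the endothelial median turned to 0.09 and the ectoderm median was -0.18 (adjusted p = 0.814 and 0.639), and the endothelial call also ended without control 1, 3 or 4 (medians of -0.61, -0.49 and -0.11, adjusted p = 0.0904, 0.118 and 0.549), with Y-linked expression as a covariate (median -0.58, adjusted p = 0.121) and when genes needed a mean of at least 1 CPM. Without heterozygous library 1 the endothelial median was -4.61 and the ectoderm median -2.26. Over 21 alternatives the adjusted p ran from 1.89e-06 to 0.86 for endothelial and 2.22e-06 to 0.745 for ectoderm genes. The endothelial median was -0.035 with the rRNA-like share as a covariate and -3.34 with the sample code number as a block. That of ectoderm genes was -1.10 with Y-linked expression as a covariate and -2.18 with the block. Microglial and macrophage genes, not called, scored 2.94 in control 4 and -2.75 in heterozygous library 2. Erythroid genes, not called, scored 1.93 in heterozygous library 1 and -3.46 in library 2, and their median of 1.39 and the camera direction differ in sign. Heterozygous library 2, which sets many of the list differences, was thus also the library lowest in endothelial, erythroid and microglial markers.

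Hypoxia and glycolysis genes were called lower (35 members, 27 below 0 and 8 above, median -0.21, camera, adjusted p = 0.0129, and 0.83 with an estimated correlation). Pdk1 stood at 55.1 ± 7.37 CPM in controls (SD, n = 4) and 35.2 ± 6.35 CPM in heterozygous cells (SD, n = 2), and the glucose transporter Slc2a1 at 128 ± 19.6 and 88.2 ± 0.271 CPM. That call ended without control 2 or heterozygous library 1 (medians of -0.16 and -0.13, adjusted p = 0.12 and 0.619), and without heterozygous library 2 the median was -0.32. It also ended without both libraries that lack Y-linked reads (median -0.045, adjusted p = 0.688) and with the sample code number as a block (median -0.078, adjusted p = 0.982). Protocadherins were called higher (34 members, median 0.27, adjusted p = 0.0216, and 0.745 with an estimated correlation), Pcdhac1 (its identifier belongs to Pcdha11 in M21) at 17.2 ± 3.96 and 28.6 ± 2.63 CPM among them, and the call ended without control 3 or heterozygous library 1 (medians of 0.24 and 0.15, adjusted p = 0.0941 and 0.325). The protocadherin call also ended with the code number as a block (median 0.02, adjusted p = 0.732), with Y-linked expression as a covariate (median 0.26, adjusted p = 0.12) and without the 2 libraries that lack Y-linked reads (median 0.21, adjusted p = 0.211). Proteasome subunits had a median of 0.08 (36 members, adjusted p = 0.0309, and 0.88 with an estimated correlation). With Y-linked expression as a covariate that median was -0.01 (adjusted p = 0.652), and the call also ended with the code number as a block (median 0.12, adjusted p = 0.219). It ended without control 1, control 3, control 4 or heterozygous library 1 (medians of 0.036, 0.018, 0.059 and -0.04, adjusted p = 0.225, 0.306, 0.0895 and 0.696). Their median was 0.24 without control 2 and 0.22 without heterozygous library 2. Over 21 alternatives the adjusted p ran from 0.00325 to 0.982 for hypoxia, 0.00741 to 0.745 for protocadherins and 1.02e-06 to 0.88 for the proteasome. In these 3 lists 0 members passed over all genes or adjusted over the list alone.

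The remaining 26 lists were not called (camera, adjusted p from 0.0621 to 0.886). Among them, exon junction complex and peripheral factors had a median log2 fold change of -0.04 (20 members, adjusted p = 0.786), nonsense-mediated decay factors -0.10 (13 members, adjusted p = 0.848) and the core spliceosome -0.04 (48 members, adjusted p = 0.886). Transcripts known to be degraded by nonsense-mediated decay, a pathway that the exon junction complex feeds, had a median of 0.02 (22 members, adjusted p = 0.131). Of these transcripts 12 were above 0 and 10 below. An unadjusted p under 0.05 (edgeR) was seen for 4, all higher, and 0 passed when adjusted over the list alone (smallest adjusted p = 0.154). Their list score was 0.16 and 0.12 in the heterozygous libraries and -0.08 to 0.11 in controls, and the difference was 0.20 within the 2 libraries without Y-linked reads and 0.11 among the other 4. Of the 15 splits of the libraries, 2 gave a score difference as large, the real one included. Apoptosis genes had a median of 0.01 (25 members, adjusted p = 0.414), with Bax at 61.7 ± 13.5 CPM in controls (SD, n = 4) and 87.0 ± 1.89 CPM in heterozygous cells (SD, n = 2). MGE patterning and progenitor genes had a median of 0.19 (25 members, adjusted p = 0.0621), and Pafah1b1, a migration gene, had a log2 fold change of 0.07 with a standard error of 0.17.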

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

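The tests of dissociation genes, of genes without reads, of the structure shared by control 2 and heterozygous library 1, and the removal of length and GC trends were chosen only after the result was seen.

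The p53 target list, with Cdkn1a, Ccng1 and Eda2r at its top, scored higher in both heterozygous libraries than in all 4 controls. Length or GC trends of single libraries are argued against as the whole cause, since the median log2 fold change was 0.27 after their removal (camera, adjusted p = 2.74e-05), though on the values as given the call was lost with an estimated correlation (adjusted p = 0.745). Stress from dissociation or sorting stays open, since the immediate early and dissociation genes went both ways (10 above 0 and 17 below, median -0.22) and were not called (adjusted p = 0.124). Of the 15 splits of the 6 libraries into 4 and 2, 1 (the real one, 0.388) gave a list score difference as large, the highest other was 0.354, and 15 splits are too few for a share under 0.05. With 41 lists scored, the real split would be the largest for some by chance, at a share of 0.0667 per list. A p53 response to the loss of a Magoh allele may account for the list and stays open as a hypothesis, beside a difference between these 6 samples that does not follow genotype.

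As lists, pan-neuronal genes were called higher and G2 and M phase genes lower in the heterozygous libraries, with 0 members of either passing edgeR (10 and 4 at an unadjusted p under 0.05, 0 called by DESeq2), and control 1 (0.43) scored above heterozygous library 1 (0.29) for the first and control 2 (-0.37) below both heterozygous libraries (-0.36 and -0.31) for the second. Removing length and GC trends left medians of 0.53 (camera, adjusted p = 3.07e-10) and -0.23 (adjusted p = 0.000178), which argues against these trends as the whole cause of either, though on the values as given both calls were lost with an estimated correlation (adjusted p = 0.745 for each). No single library decided the G2 and M phase call, with adjusted p of at most 0.0413 when each of the 6 was left out, but heterozygous library 1 differed from control 2 by 0.018 in that score, so the structure that these 2 libraries share could account for its low value there. With Y-linked expression as a covariate the pan-neuronal median was 0.58 (camera, adjusted p = 5.86e-11). That covariate gives these 2 libraries the same value. Their drop of long against short transcripts was unequal, at -0.81 log2 units in control 2 and -0.34 in heterozygous library 1. For pan-neuronal genes the fit therefore argues against a structure of equal strength in both libraries. It leaves one of unequal strength open. The G2 and M phase median of -0.23 in that fit (camera, adjusted p = 9.5e-05) rests on heterozygous library 2 (-0.43 against controls 1, 3 and 4) and leaves the structure open. A shift from dividing to differentiating cells in heterozygous embryos, or a difference in embryo stage or in the sorted population, stays open and was not tested further.

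Genes without a read in both heterozygous libraries make up 31 of the 68 lower DESeq2 calls. A further 33 had a control mean of at least 1 CPM and more than 2 reads in a heterozygous library. The test of genes at 0 does not cover those 33. Of genes with at least 10 reads in each control, 22 had 0 reads in both heterozygous libraries. Independent dropout gave an expected 10.4, a ratio of 2.12. The expectation was computed within bins of genes of similar mean reads in the libraries outside the pair. A larger ratio to that expectation appeared for control 2 with heterozygous library 1 (13 against 3.6) and with heterozygous library 2 (16 against 4.8), pairs that do not follow genotype. Fewer distinct molecules in these libraries and a loss of expression in heterozygous cells therefore cannot be told apart for these genes, because both heterozygous libraries also had the highest shares of genes at 0.

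List score differences as large as the real one were given by other splits of the 6 libraries for most called lists. Counting the real split, 3 of 15 did so for pan-neuronal genes (0.481, highest other 0.626), 5 for G2 and M phase (-0.331, highest other 0.394 in size), 6 for histones, 6 for the spindle list, 4 for DNA repair, 3 for interneurons, 2 for Wnt and 5 for hedgehog genes. The count was 3 for surface ectoderm, 7 for endothelium, 2 for hypoxia, 3 for protocadherins and 11 for the proteasome. For p53 targets and S phase genes (-0.198, highest other 0.177 in size) it was 1, the real split. By chance the real split would be the largest in a share of 0.0667 of lists, and 41 lists were scored. A count of 1 therefore does not set these lists apart.

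As many genes as the 75 of the real comparison were called by DESeq2 in 2 of the 15 splits, the real one included, and 15 splits are too few for a share under 0.05. The highest other count, 3372, came from control 2 and heterozygous library 1 against the other 4, which points to a structure of the samples. For that split edgeR called 2136 genes, 781 higher and 1355 lower in the 2 libraries, with median exon lengths of 2911 and 7877 nt, against 4077 nt for all tested genes. Of these calls 83 lay on the X or Y chromosome, and after removing length and GC trends 825 calls were made. With Y-linked expression as a covariate edgeR called 0 genes between genotypes (1854 at an unadjusted p under 0.05), and without these 2 libraries it called 0 (3052 at an unadjusted p under 0.05), where DESeq2 on all 6 called 75.

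Among 110 values tested for a control far from the other 3, 11 stood out, where chance gives about 5.5. These values are not independent, since Xist, Ddx3y, Kdm5d and Uty flag the same trait of control 2, so the excess over chance cannot be judged. Control 2 had an Xist level of 94.2 CPM, with at most 0.0442 CPM in the others, and 0 CPM of Ddx3y, Kdm5d and Uty, against 20.1 to 22.4, 37.1 to 42.2 and 16.6 to 19.3 CPM. Control 2 also had 38.2 CPM of the proteasome assembly gene Psmd9, against 25.6 to 27.6 CPM. Control 3 had 10.65 CPM of Cdkn1a, against 4.42 to 4.64 CPM in the other controls, and remained below both heterozygous libraries (16.9 and 28.3 CPM). It also had 26.9 CPM of Crb1, against 34.8 to 35.9 CPM, and 21.8 CPM of Nhlh1, against 34.8 to 35.8 CPM. Control 4 had 16.65 CPM of Fgf8, against 7.12 to 8.66 CPM, and 384 CPM of Mcm6, against 343 to 349 CPM. Its globin transcripts were 0.0137% of counts, against 0.0031 to 0.0046%.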

How the results depend on the processing

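The length and GC removal, the rRNA-like share as a covariate and leaving out both libraries without Y-linked reads were chosen only after the result was seen. The count of 0 changed genes (edgeR, 944 at an unadjusted p under 0.05) held in all but 2 of 23 alternatives. DESeq2 called 75 (7 higher, 68 lower). With the sample code number as a block edgeR called 11, all lower (among them Slc4a1, Cd34, Csf1r, Tfap2b, Fam151b, Hbb-y, Hbb-bh1, Hba-x, Mab21l2 and Hba-a1), and only 1 code number holds both genotypes. Hbb-y turned sign there, to -7.58 from a log2 fold change of 1.67 in the main fit. Heterozygous library 2, on which that block rests together with control 1, had the lowest erythroid score (-3.46). The 15 called lists became 0 by camera with an estimated correlation and 0 by fry. In the other alternatives 11 to 20 lists were called. Pan-neuronal and G2 and M phase lists were called in 19 of 21 alternatives, all but those 2 tests. The Magoh log2 fold change stayed between -0.73 and -0.37 in 21 alternatives.

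Beside Hbb-y, signs turned for genes that did not pass. With the code number as a block the Magohb log2 fold change was -0.022, Nkx2-1 0.036, Pafah1b1 -0.042 and Trp53 0.17. With Y-linked expression as a covariate Magohb was -0.11, Ddx3y 0.33, Eif2s3y 0.14 and Kdm5d 0.23. That covariate sums the reads of Ddx3y, Eif2s3y, Kdm5d and Uty, so their own values in that fit do not measure genotype. Without the 2 libraries Nkx2-1 was 0.056 and Trp53 0.19. Leaving out each library in turn gave ranges of -0.20 to 0.31 for Magohb, -0.32 to 0.12 for Nkx2-1, -0.23 to 1.56 for Lhx6 and -0.85 to 0.21 for Trp53. The ranges were -5.40 to 11.06 for Xist, -12.34 to 0.39 for Ddx3y, -11.47 to 0.23 for Eif2s3y, -13.28 to 0.27 for Kdm5d and -4.61 to 0.088 for the endothelial median. Fitted values of sex-linked genes at 0 in a group depend on the prior count. Without heterozygous library 2 the heterozygous library left has 0 Y-linked reads, which gives the -12.34 of Ddx3y. Without control 2 the controls have at most 0.0442 CPM of Xist, which gives its 11.06. For the genes that are not sex-linked, apart from fewer samples, the cause was not tested. Where 1 heterozygous library was left, it was assumed to vary like the controls. At this size edgeR recovered 22% of simulated 2-fold changes, so changes of that size are mostly not detectable.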

Other observations

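The values of 2410006H16Rik were chosen for description after they were seen, and the other values here belong to lists fixed earlier.

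Preoptic area and hypothalamus genes went both ways and were not called (25 members, 13 above 0 and 12 below, median 0.13, camera, adjusted p = 0.12). Their score differed by 0.46 within the 2 libraries without Y-linked reads and by -0.15 among the other 4. Beside Sim1 and Nkx2-2, Otp stood at 40.5 CPM in controls (n = 4) and 73.4 CPM in heterozygous cells (n = 2), and 0 members passed edgeR when adjusted over the list alone (smallest adjusted p = 0.0535), with 6 at an unadjusted p under 0.05 and 1 called by DESeq2. Notch signalling genes went both ways (19 members, median -0.09, adjusted p = 0.786). The ligand Dll3 stood at 119 CPM in controls and 178 CPM in heterozygous cells, while Hes1, a Notch effector of progenitors, had a log2 fold change of -0.72. Radial glia and neural progenitor genes had a median of -0.16 (25 members, adjusted p = 0.193), with Slc1a3 at a log2 fold change of -0.74. Dorsal telencephalon genes had a median of 0.12 (23 members, adjusted p = 0.124), and lateral and caudal ganglionic eminence genes one of 0.13 (21 members, adjusted p = 0.211).

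Small nucleolar RNA host genes had a median of 0.23 and a mean near 0 (7 members, camera, adjusted p = 0.461). Among them Snhg12 stood at 2.42 CPM in controls and 8.35 CPM in heterozygous cells and passed when adjusted over the list alone (edgeR, adjusted p = 0.0492), but not over the list of nonsense-mediated decay targets that also holds it (adjusted p = 0.154). The non-coding 2410006H16Rik on chromosome 11 stood at 7.07 ± 1.86 CPM in controls (SD, n = 4) and 33.7 ± 14.7 CPM in heterozygous cells (SD, n = 2), and DESeq2 called it higher while edgeR did not. Its unadjusted edgeR p of 0.000104 was below that of every ranked gene (smallest 0.000189, Frzb), and its clone name left it out of that ranking. Strandedness is not given, so reads of antisense transcripts are not separated there.

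Other lists not called by camera had medians of 0.04 for cytosolic ribosomal proteins (adjusted p = 0.0621), 0.03 for the nuclear-encoded respiratory chain (adjusted p = 0.142) and -0.22 for mitochondrial mRNAs (adjusted p = 0.193). Immediate early and dissociation genes had a median of -0.22 (adjusted p = 0.124), heat shock proteins -0.04 (adjusted p = 0.587), and the integrated stress and unfolded protein response -0.06 (adjusted p = 0.786). Microglia and macrophages had a median of -1.34 (adjusted p = 0.156), erythroid cells 1.39 (adjusted p = 0.308), pericytes and mesenchyme -0.08 (adjusted p = 0.217), and interferon response genes -0.08 (adjusted p = 0.414). Medians were -0.10 for oligodendrocyte precursors and glia (adjusted p = 0.786), -0.05 for cholesterol synthesis (adjusted p = 0.786), -0.74 for sex-linked genes (adjusted p = 0.786) and -0.07 for cholinergic and globus pallidus lineages (adjusted p = 0.848).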
